A study of Mus musculus with 6 samples.

How the data were processed

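RNA bound to ribosomes was profiled by translating ribosome affinity purification (TRAP) in the thalamus of adult, untreated mice of the Cbln1-EGFP/Rpl10a line NIDA030. In TRAP, a ribosomal protein (here Rpl10a) tagged with green fluorescent protein is made in chosen cells, and the tagged ribosomes are pulled down from a tissue homogenate with antibodies against the tag. The series held 6 libraries: 3 immunopurified (IP) and 3 Input. Per the labels' protocols the IP came from tagged polysomes of dissected thalamus, and the labels gave the molecule of both kinds of library as ribosome-bound RNA. The names under which the counts were deposited point to the parafascicular nucleus, a part of the thalamus, while the labels name only the thalamus. The labels were used, so how much of the thalamus and its neighbours the samples held is uncertain. Groups were taken from the sample-type label and replicate numbers from the titles. Nothing in the labels says that replicates came from separate animals or pools. Xist, the RNA of the inactive X chromosome, had 165, 311 and 0 counts in Input replicates 1 to 3 and 87, 34 and 0 in IP. The choroid plexus gene Ttr had 71, 24784 and 28317 counts in Input and 0, 1861 and 1490 in IP. These values argue against replicates that repeat 1 tissue sample. P-values measure only the spread between these samples, and the number of animals behind it is unknown.

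The deposited values were raw read counts per gene, 1 column for each library. Per the submitters' processing notes, reads were aligned with STAR 2.0.0e to the mouse build mm10 and counted with HTSeq. The HTSeq version, its strand setting and the gene annotation were not given in the sources used here, so reads of overlapping or antisense genes could not be told apart. Each file closed with 5 lines tied to no gene, of which 2 were 0 in every library. These lines, and a line named unknown that held at most 1 count, were left out of library sizes and tests. As a share of all lines, reads set aside as not uniquely aligned made up 45.9 ± 3.39% in IP and 33.3 ± 0.687% in Input (SD, n = 3 each). Reads outside annotated features made up 8.87 ± 0.478% and 15.4 ± 0.591%, and reads that overlapped several features 1.48 ± 0.140% and 5.89 ± 0.622%. For these shares the exact two-sided permutation p was 0.1 each, the smallest that 3 against 3 libraries allow. The sources used did not say whether a read with several alignments was counted once or more often. These values may therefore not be shares of reads.

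Assigned counts came to 23929070, 47741219 and 47439665 in Input replicates 1 to 3 and to 57385828, 48067129 and 45256700 in IP replicates 1 to 3. Replicates differed by more than sampling noise in every pair, with chi-square per degree of freedom between 11.8 and 134, so each library counted as 1 sample. The 45S ribosomal RNA precursor Rn45s took 11.2 ± 2.86% of assigned counts in IP and 5.33 ± 0.103% in Input. No ribosomal or mitochondrial genes were removed, and the files held no row with a mitochondrial gene prefix.

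Genes were tested in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Of 32531 named genes, 16898 passed filterByExpr (minimum count 10). Library sizes were scaled by trimmed mean of M-values (TMM), and IP was compared with Input by edgeR's robust quasi-likelihood F-test. Every adjusted p-value of a gene is from this test with Benjamini-Hochberg adjustment, with a threshold of 0.05. Standard errors (SE) of log2 fold changes were derived from the F statistic, and mean CPM (counts relative to library size) are TMM-scaled. For a group at 0 counts, fold changes were bounded with a floor of 3 counts over the group. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with the correlation estimated from the data, and with fry. All lists with at least 3 tested members formed 1 family for adjustment. On counts simulated from the means of the Input libraries (16641 genes), the test found 13.4% of 67 genes changed 1.5-fold, 51.5% of 66 changed 2-fold and 70.8% of 65 changed 4-fold. The simulated changes included the 20 members of a list raised 2-fold, and 7 of the 116 calls were false (6.03%). Far fewer genes changed there than were called in the real comparison, and the adjustment depends on that number, so these shares may not hold for it.

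The design, the test, the 24 gene lists and the rule for named genes were fixed before the data were examined. The rule took Cbln1 and Rpl10a, the 10 largest and 10 smallest called log2 fold changes with a mean of at least 5 CPM and no overlap between groups, and for each list the 2 most changed called members at that level plus the most significant one in the opposite direction. For a list with no such member it took the 2 members of highest CPM. Further genes named in the text, and the symbol Inadl in place of Patj, were chosen after their values were seen. Some genes are not reported here. Genes were placed on the GENCODE annotation of the same build, which held 15292 of the tested genes (90.5%) by symbol.

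Replicate numbers were treated as pairing the IP and Input libraries, because the labels give each number its own sequencing lane code, shared by IP and Input. This was read from the labels, with the counts of calls of both fits already known. Over 10788 genes, deviations from the group means correlated between the IP and Input library of the same number at 0.154, 0.0512 and 0.0417, and IP replicate 2 correlated more with Input replicate 3 (0.0686). Only the correlation of number 1 was above 0.1, the value set as needed for pairing. The pairing therefore rests on the labels, and a shared lane code does not show a shared homogenate. Xist had 165, 311 and 0 counts in Input replicates 1 to 3 and 87, 34 and 0 in IP replicates 1 to 3. The fixed design had no block, and the fit with the replicate number as a block was the alternative. Other alternatives were relative log expression (RLE), upper-quartile and library-total scaling, factors without ribosomal protein and haemoglobin genes, no filter and a stricter filter (at least 1 CPM in 3 libraries and a mean of 5 CPM), DESeq2 1.42.0, limma-voom, a test against a fold of 1.5, and leaving out each library or each replicate number. Scaling without Rn45s was added after the data were seen. List medians and counts cover the members each setting tested, so those with another filter, with DESeq2 or with libraries left out may cover other members.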

Results

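The data were RNA-seq read counts per gene from 6 mouse libraries, 3 IP and 3 Input, from the thalamus of the Cbln1 TRAP line. IP stands for the RNA recovered with the tagged ribosomes, and Input for the libraries the labels call input; the labels give ribosome-bound RNA for both. Assigned counts ran from 23929070 (Input replicate 1) to 57385828 (IP replicate 1). The ribosomal RNA precursor Rn45s made up 11.2 ± 2.86% of them in IP and 5.33 ± 0.103% in Input (SD, n = 3 each). The design implies 1 comparison, IP against Input, which asks which RNAs were enriched by the pull-down of tagged ribosomes.

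Cbln1, a secreted organiser of synapses and the gene for which the line is named, was 17.9-fold higher in IP. It reached 1429 ± 67.8 CPM in IP and 79.8 ± 9.64 CPM in Input (SD, n = 3 each), a log2 fold change of 4.16 (SE 0.11, adjusted p = 9.66e-08), with log2 ratios of 4.30, 4.10 and 4.10 in the replicate numbers. The gene lies on chromosome 8 at 87468405 to 87472609 (mm10). Increases were ranked among called genes with a mean of at least 5 CPM and no overlap between groups. The next largest increases were in Slc35d3 (log2 fold change 3.90, SE 0.37), Ctxn3 (725 CPM in IP, 51.9 in Input, adjusted p = 2.50e-07), the long non-coding RNA Gm2694 (3.75, SE 0.15), Lypd6 (3.64, SE 0.10), 1700011I03Rik (3.62, SE 0.26), the protease gene Bace2 (3.59, SE 0.27), Lypd6b (3.51, SE 0.18), Rprm (3.45, SE 0.20) and the Cbln1 relative Cbln4 (3.43, SE 0.09). Adjusted p-values of these genes lay between 9.66e-08 (Lypd6, Cbln4) and 4.46e-05 (Slc35d3). Rpl10a, the tagged ribosomal protein, did not differ beyond the replicate spread (5.12 ± 0.968 CPM in IP, 4.88 ± 0.178 in Input, log2 fold change 0.07, SE 0.28, adjusted p = 0.857). Its unique count is uncertain because near-identical copies exist in the genome.

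Several of these genes were neighbours. Gm2694 (chromosome 8, 87460469 to 87525554, plus strand) spans Cbln1 on the opposite strand, and the 2 share 0 exonic bases. Lypd6b and Lypd6 follow each other on chromosome 2 (49787688 to 49948849 and 50066429 to 50193569), and so do Ctxn3 and 1700011I03Rik on chromosome 18 (57468516 to 57478133 and 57533780 to 57731065). Zfp423, a zinc finger gene farther along chromosome 8 (87661810 to 87959595), was also higher in IP (2.84-fold, adjusted p = 6.75e-06). Zfp423 was named after its value was seen. Counts of Gm2694 were at least 7.52% of those of Cbln1 in each Input library and 5.60 to 7.79% in IP, and a contribution of Cbln1 reads to them was not excluded.

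**Figure D1:**
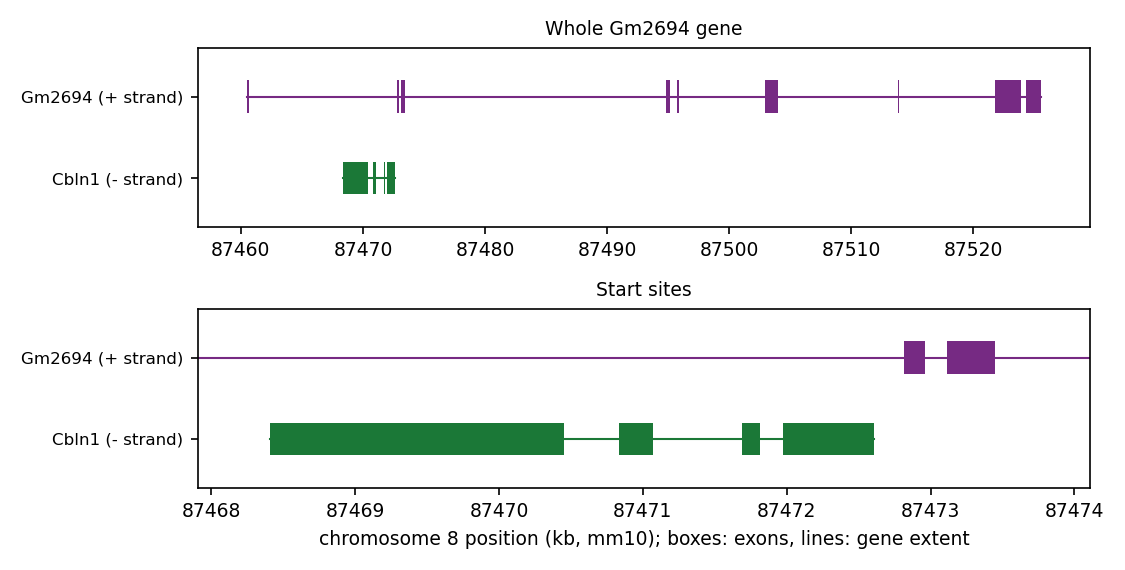
Gene map of chromosome 8 in kb (mm10), with exons as boxes and gene extents as lines, for Cbln1 (minus strand) and Gm2694 (plus strand). The upper panel shows the whole of Gm2694 and the lower panel the start sites, where the nearest annotated Gm2694 transcript starts 203 bp from the start of Cbln1.

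Of 16898 genes tested, 3930 (23.3%) were higher and 4100 (24.3%) lower in IP. Decreases were larger: 3109 genes were at least 2-fold and 1607 at least 8-fold lower, against 1111 and 52 higher. Of all calls, 8011 (99.8%) had the same sign in all 3 replicate numbers, each of which is also a lane. Calls were picked by a test on these same libraries, which favours agreement in sign, so this share is no separate support. The IP and Input values did not overlap for 10410 genes (61.6%), where chance gives 10%. Higher genes made up 48.9% of calls under TMM, 36.7% under upper-quartile and 31.9% under library-total scaling, where the median of all genes shifted by -0.18 and -0.24 from -0.07. Library totals alone called 2458 genes higher, and a test against a 1.5-fold change called 1484 higher and 2700 lower.

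Of 23 gene lists tested with camera, 4 were higher in IP, 11 were lower and 8 were not called. With an estimated correlation, only the astrocyte and oligodendrocyte lists kept their calls. Fry called 5 lists up and 14 down. Counts adjusted over the list alone were the same as over all genes for every list except cytosolic ribosomal proteins (13 higher, 2 lower), oxidative phosphorylation (67 higher, 4 lower), microglia (14 lower) and glutamate and GABA-A receptors (11 higher, 8 lower). Medians of lists with members at 0 counts in a group did not move when those members were set at their bound. Of the list members, 12 stood on 2 lists.

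**Figure D2:**
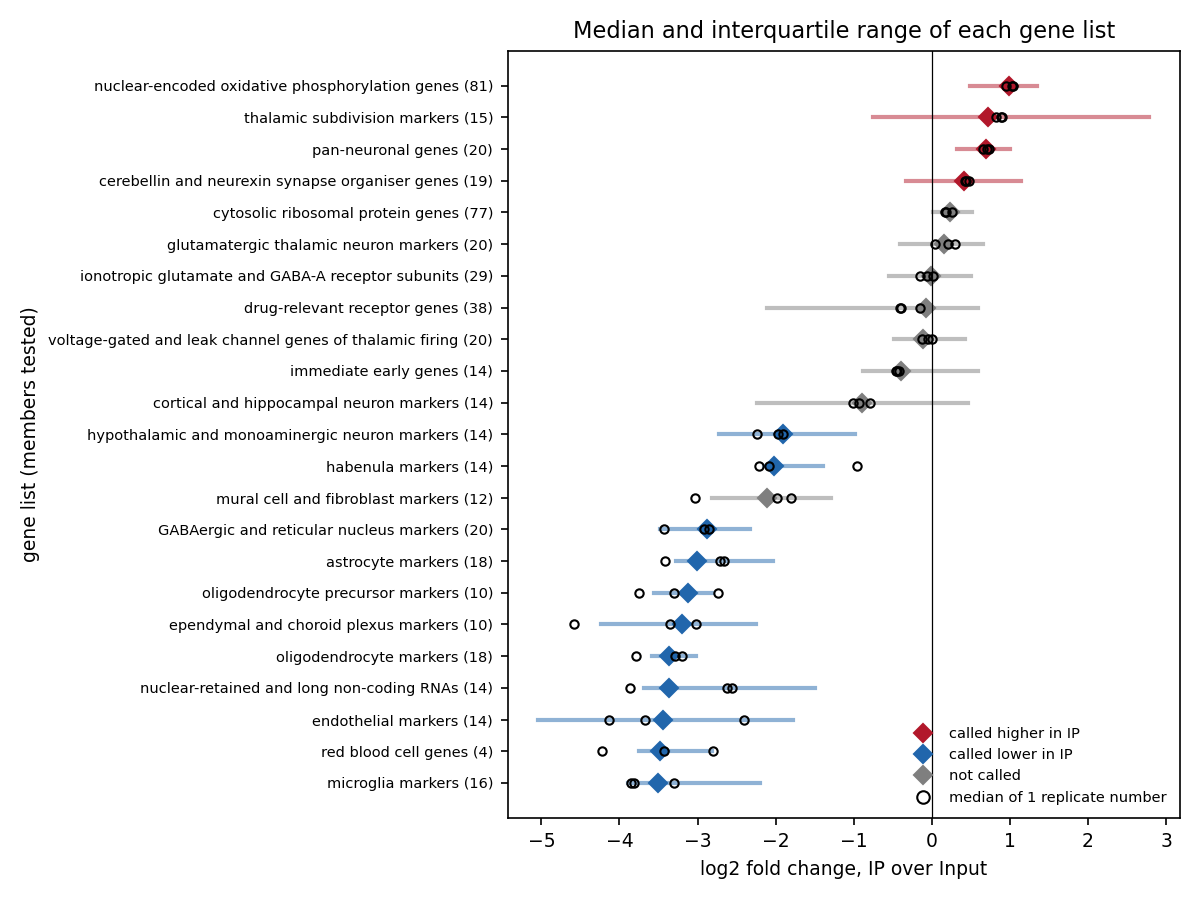
Median log2 fold change of IP over Input (diamonds) and interquartile range (bars) of each gene list, with the median in each replicate number as open circles. Lists called higher (red) had medians between 0.41 and 0.99, and lists called lower (blue) between -3.51 and -1.91.

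Neuronal genes were higher in IP. Of 20 pan-neuronal genes 15 rose, led by the stathmin gene Stmn3 (log2 fold change 1.36, SE 0.09, adjusted p = 5.49e-06) and the ubiquitin hydrolase gene Uchl1 (1.28, SE 0.13, adjusted p = 5.08e-05). The synaptic vesicle fusion gene Snap25 rose from 9301 ± 455 to 19373 ± 2462 CPM. The list's median was 0.70 (camera adjusted p = 6.47e-06, but adjusted p = 0.0914 with an estimated correlation). Syn2, a vesicle-associated phosphoprotein (-2.19, SE 0.15), and Map2, a dendritic microtubule protein (-1.09, SE 0.09), fell.

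Markers of thalamic neurons split. Among 20 markers of glutamatergic thalamic neurons, 8 rose, among them Foxp2 (log2 fold change 2.09, SE 0.16), the vesicular glutamate transporter Slc17a6 (1.06, SE 0.13) and the transcription factor Tcf7l2 (0.84, SE 0.10). Inadl (-2.88), Zic4 (-1.40), Ntng1 (-0.67), Zic1 (-0.43) and Rora (-0.40) fell. Levels of Prkcd (512 CPM in IP, 471 in Input, adjusted p = 0.456) and Cacna1g (91.5 and 90.8 CPM, adjusted p = 0.931) did not pass. The list was not called (median 0.15, adjusted p = 0.499), and its median was -0.03 under upper-quartile and -0.09 under library-total scaling, 0.01 under the stricter filter and 0.22 without Input replicate 2. Zic1 lost its call without IP replicate 2 or 3, Input replicate 2 or 3, and replicate number 2 or 3 (adjusted p between 0.0541 and 0.183).

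Genes that mark subdivisions of the thalamus moved far in both directions. Besides Lypd6b and Cbln4, the peptide genes Pdyn (log2 fold change 3.27, SE 0.20) and Grp (3.34, SE 0.24), Cbln2 (2.30, SE 0.14), the calcium-binding protein Calb1 (1.25, SE 0.12) and Spon1 (1.10, SE 0.16) rose, 7 of 15 in all. Tnnt1 (-2.94, SE 0.32), Necab1 (-2.53, SE 0.16), Calb2 (-2.03, SE 0.19) and the peptide Cck (-0.92, SE 0.15) fell. Pdyn went from 4.42 ± 1.10 to 42.9 ± 2.09 CPM, and Necab1 from 253 ± 37.4 to 43.9 ± 8.30 CPM. The list was called higher (median 0.72, adjusted p = 2.33e-04, but adjusted p = 0.0810 with an estimated correlation). Its median was 0.32 without IP replicate 1, 0.39 without Input replicate 3 and 0.47 under library totals.

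Synapse organisers around the cerebellins, which join presynaptic neurexins to postsynaptic delta-type glutamate receptors, were higher as a list. Cbln1, Cbln4, Cbln2, the delta receptor Grid1 (log2 fold change 1.42, SE 0.15) and Lrrtm3 (1.11, SE 0.12) were among 10 of 19 members that rose. C1ql2 (-3.39), C1ql1 (-1.84), the neurexin Nrxn3 (-1.07) and the neuroligin Nlgn1 (-0.53) fell. The list had a median of 0.41 (adjusted p = 2.14e-05, but adjusted p = 0.111 with an estimated correlation), and it holds the gene for which the line is named. Its median was 0.23 under upper-quartile and 0.18 under library-total scaling. Nlgn1 lost its call without Input replicate 1 and without replicate number 1 or 2 (adjusted p between 0.0779 and 0.123), and C1ql2 without replicate number 1 (adjusted p = 0.0552).

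Astrocyte and oligodendrocyte genes fell. All 18 astrocyte markers were lower, among them the receptor Fgfr3 (log2 fold change -4.18, SE 0.44), the filament protein Gfap (-3.95, SE 0.35), the water channel Aqp4 (-3.14, SE 0.23) and the glutamine synthetase Glul (-2.19, SE 0.09), while the glutamate transporter Slc1a2 fell least (-0.85, SE 0.08). All 18 oligodendrocyte markers were lower too: Ermn (-4.00, SE 0.13), Cldn11 (-3.74, SE 0.18), and the myelin genes Mobp (-3.72, SE 0.12) and Mbp (-3.53, SE 0.14). Mbp went from 1163 ± 80.3 CPM in Input to 101 ± 18.5 CPM in IP. Median log2 fold changes were -3.01 for astrocytes (adjusted p = 1.98e-17, and 0.0314 with an estimated correlation) and -3.37 for oligodendrocytes (adjusted p = 8.57e-57, and 0.0427 with an estimated correlation).

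Oligodendrocyte precursor and microglial markers were lower as well. Sox10 (log2 fold change -3.81, SE 0.39) and Olig1 (-3.64, SE 0.14), transcription factors of the oligodendrocyte lineage, were among 9 of 10 precursor markers that fell, and Lhfpl3 rose (2.22, SE 0.14, from 59.8 ± 2.38 to 279 ± 55.9 CPM). The precursor list had a median of -3.13 (adjusted p = 1.25e-05, but adjusted p = 0.111 with an estimated correlation). Of 16 microglial markers 12 fell, among them the fractalkine receptor Cx3cr1 (-4.10, SE 0.54), the protease Ctss (-4.20, SE 0.99) and the growth factor receptor Csf1r (-2.42, SE 0.77). Their median was -3.51 (adjusted p = 0.00140, but adjusted p = 0.0914 with an estimated correlation, and 0.268 under the stricter filter). Ctss lost its call without replicate number 3 (adjusted p = 0.0592), and Csf1r without IP replicate 2, any 1 Input library or replicate number 2 (adjusted p between 0.0655 and 0.159).

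**Figure D3:**
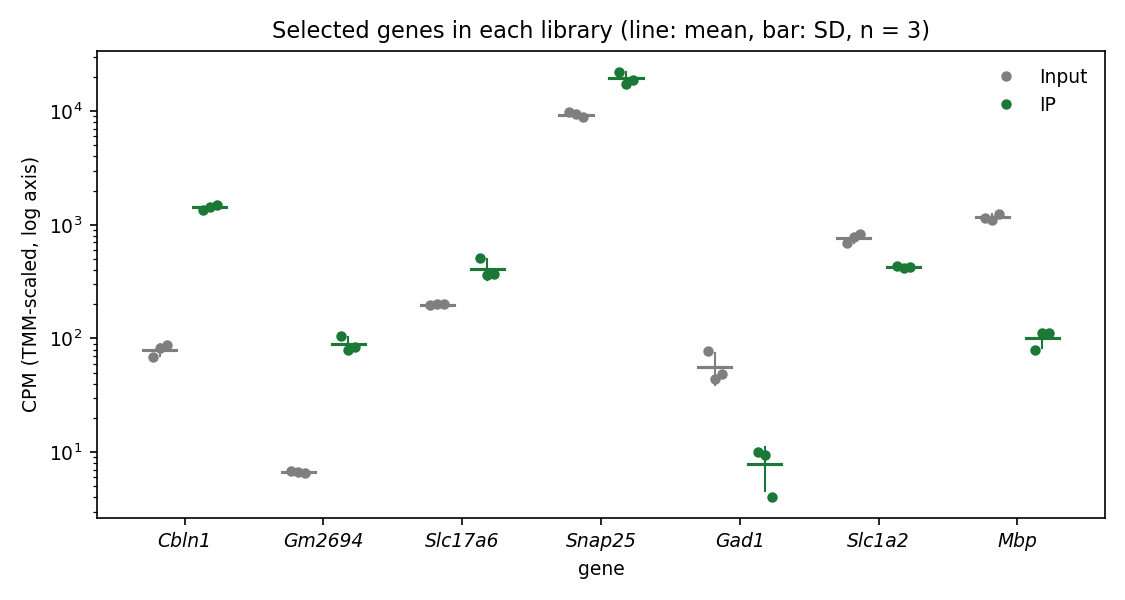
CPM (TMM-scaled, log axis) of selected genes in each of the 3 Input (grey) and 3 IP (green) libraries, with the mean as a line and the SD as a bar. Cbln1 rose 17.9-fold in IP, while Mbp went from a mean of 1163 to 101 CPM.

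Inhibitory neurons and neurons of neighbouring regions were lower in IP. Of 20 GABAergic and reticular nucleus markers 15 fell, including the transcription factors Six3 (log2 fold change -4.24, SE 0.29) and Otx2 (-3.55, SE 0.32) and the GABA-synthesising enzymes Gad2 (-3.12, SE 0.15) and Gad1 (-2.84, SE 0.34). The peptide gene Npy rose (2.56, SE 0.22, 3.06 ± 0.520 to 18.1 ± 2.01 CPM), and Pvalb did not pass (44.0 CPM in IP, 49.7 in Input, adjusted p = 0.428). The list's median was -2.87 (adjusted p = 7.66e-08, but adjusted p = 0.111 with an estimated correlation). In the habenula list 11 of 14 fell, among them the nicotinic receptor subunits Chrnb3 (-3.68, SE 0.34) and Chrna3 (-2.78, SE 0.41) and the tachykinin gene Tac1 (-2.15, SE 0.33), with a median of -2.02 (adjusted p = 2.33e-04, but adjusted p = 0.251 with an estimated correlation).

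Some hypothalamic and monoaminergic markers fell in the same comparison. Of 14 hypothalamic and monoaminergic markers 7 were lower, including the dopamine transporter Slc6a3 (log2 fold change -4.16, SE 0.43), the decarboxylase Ddc (-2.74, SE 0.35) and tyrosine hydroxylase, Th (-1.90, SE 0.19). The list's median was -1.91 (adjusted p = 0.0103, but adjusted p = 0.396 with an estimated correlation). It was -1.07 without Input replicate 1 and -2.79 without IP replicate 1. Pmch, the melanin-concentrating hormone gene, had 6.50, 0.674 and 0.344 CPM in Input replicates 1 to 3 and 19.9, 0.109 and 0 CPM in IP replicates 1 to 3. It was not called with all libraries (1.45, adjusted p = 0.529) and was lower without IP replicate 1 (-5.39, adjusted p = 0.0237).

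Cortical and hippocampal markers were not called as a list (median -0.89, adjusted p = 0.321, with medians of -0.48 to -0.37 without any 1 Input library, IP replicate 1 or 3, or replicate number 3, -0.10 under the stricter filter and -1.38 with DESeq2). The stricter filter and DESeq2 covered other sets of its members. Of 14 tested in the main fit, 6 fell, including Bcl11b (log2 fold change -2.03, SE 0.45) and Rasgrf2 (-1.34, SE 0.15). The kinase Camk2a (0.53, SE 0.09), the vesicular glutamate transporter Slc17a7 (0.48, SE 0.14) and Lamp5 (1.28, SE 0.38) rose. Slc17a7 lost its call under upper-quartile scaling, library totals and the stricter filter (adjusted p between 0.0797 and 0.234) and without Input replicate 1 or 3 or replicate number 3 (between 0.0598 and 0.114). Lamp5 lost its call under library totals (adjusted p = 0.0554) and without IP replicate 3, any 1 Input library, or replicate number 2 or 3 (between 0.0601 and 0.182).

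Vascular, ependymal and blood genes were lower in IP. In the endothelial list 10 of 14 fell (median -3.44, adjusted p = 0.0108, but adjusted p = 0.251 with an estimated correlation), and the glucose transporter Slc2a1 went from 26.0 ± 0.719 to 14.6 ± 3.74 CPM (log2 fold change -0.84, SE 0.20). The tight junction gene Cldn5 had 0 counts in all IP libraries and 0.475 CPM in Input. Of 10 ependymal and choroid plexus markers 6 fell (median -3.20, adjusted p = 0.0103, but adjusted p = 0.223 with an estimated correlation), including Foxj1 (-2.05, SE 0.26) and Clic6 (-2.21, SE 0.41). The haemoglobin genes Hbb-bs (-4.29, SE 0.27), Hbb-b2 (-3.57, SE 0.60) and Hba-a2 (-3.39, SE 0.68) fell, 3 of 4 tested (median -3.48, adjusted p = 0.0103, but adjusted p = 0.135 with an estimated correlation). Under the stricter filter the ependymal list lost its call (adjusted p = 0.207) and the endothelial (median -0.99) and red blood cell lists kept too few members for a test. The ependymal median was -4.90 with limma-voom. Slc2a1 lost its call without replicate number 3 (adjusted p = 0.0645). Near-identical haemoglobin copies make their counts uncertain.

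Mural cell and fibroblast markers were not called as a list (median log2 fold change -2.11, adjusted p = 0.113, and 0.254 with an estimated correlation). At the preset correlation the list was called lower with the replicate number as a block (adjusted p = 0.0278) and without replicate number 3 (adjusted p = 0.0386). Its median was -1.11 under the stricter filter and -3.24 with limma-voom. Of 12 markers, Rgs5 (-2.88, SE 0.50), Vtn (-2.79, SE 0.63), Myl9 (-2.56, SE 0.61), Abcc9 (-3.43, SE 1.06) and Lum (-3.27, SE 0.92) fell, and the growth factor receptor Pdgfrb rose (0.98, SE 0.27). Lum lost its call with the block (adjusted p = 0.0770) and without any 1 Input library or replicate number 2 or 3 (between 0.0555 and 0.0936). Abcc9 lost it without Input replicate 1 or 2 or replicate number 1 or 2 (between 0.0665 and 0.122), and Pdgfrb without Input replicate 3, replicate number 2 or 3, and under library totals (0.0528 or more). The choroid plexus genes Ttr (-3.76, adjusted p = 0.257), Kl (-2.37, adjusted p = 0.117) and Kcne2 (-2.81, adjusted p = 0.183) were not called. With the block, Ttr (adjusted p = 3.07e-06), Kl (adjusted p = 0.00220) and Kcne2 (adjusted p = 0.0322) were called lower, as Ttr and Kl were without replicate number 1 (4.29e-05 and 0.00599).

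Nuclear and long non-coding RNAs were lower in IP. Of 14 such RNAs 12 fell, including Meg3 (log2 fold change -4.14, SE 0.18), Miat (-4.10, SE 0.15), the abundant nuclear RNA Malat1 (-3.90, SE 0.18, 28322 ± 2944 to 1903 ± 458 CPM) and Snhg11 (-3.41, SE 0.12). Peg13 (0.96, SE 0.08) and Pantr1 (0.82, SE 0.21) rose. The list's median was -3.37 (adjusted p = 9.01e-15, but adjusted p = 0.0810 with an estimated correlation). Over all annotated long non-coding genes, 215 of 719 fell and 47 rose (median -0.75), against 3196 lower and 3813 higher of 14416 protein-coding genes (median 0.02). Pantr1 lost its call without Input replicate 3 and without replicate number 1 or 3 (adjusted p between 0.0552 and 0.115).

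Decreases were ranked among called genes with a mean of at least 5 CPM and no overlap between groups, and genes of fewer counts can have larger ones. Most of the 10 largest in that ranking were in transcripts named only by a sequence identifier that matched no annotated gene symbol. They were led by GU332589 (log2 fold change -6.17, SE 0.36) and DQ539915 (-6.01, SE 0.21). Matching was by name, so whether such transcripts lie within annotated genes was not examined. AK140265 went from 52444 CPM in Input to 1413 CPM in IP (-5.21, SE 0.20). The annotated genes among them were Gdap10 (-6.57, SE 0.66), C030029H02Rik (-5.34, SE 0.46) and Srrm4os (-4.98, SE 0.67), and the others were AK162351 (-5.52), AK134750 (-5.29), AK015545 (-5.07) and AK043676 (-4.94). Of the 1606 tested genes whose name matched no annotated symbol, 651 fell and 63 rose (median -1.46). The ribosomal RNA precursor Rn45s rose (1.32, SE 0.18, adjusted p = 3.12e-04).

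Nuclear genes of oxidative phosphorylation, the respiratory chain and ATP synthase of mitochondria, rose together. Of 81 tested, 65 were higher, among them Ndufa4 (log2 fold change 1.76, SE 0.10, 169 to 572 CPM) and Cox7c (1.75, SE 0.17). Cox6a2 (-3.15, SE 0.25), Cox6b2 (-1.65, SE 0.49) and Cox8b fell. The last of these had 0 counts in IP (bounded log2 fold change -4.29). The ATP synthase subunit Atp5b (1629 CPM in IP, 1787 in Input, adjusted p = 0.258) and the complex I subunit Ndufs1 (86.1 and 85.5 CPM, adjusted p = 0.936) did not pass. The list's median was 0.99 (adjusted p = 8.06e-24, but adjusted p = 0.0914 with an estimated correlation). Over 4 classes of coding genes by exonic length, the median was 0.26 in the shortest and -0.14 in the longest. Cox6b2 lost its call without any 1 Input library or replicate number (adjusted p between 0.0619 and 0.103), and Atp5b was called lower without IP replicate 2 (0.0205), under upper-quartile scaling (0.0179), library totals (0.0245) and the stricter filter (0.0188).

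Few cytosolic ribosomal protein genes passed the test. Of 77 tested, 15 rose, including Rps27l (log2 fold change 1.42, SE 0.33) and Rpl34 (1.23, SE 0.16), and Rpl9 (-2.02, SE 0.61), Rps4x (-0.71, SE 0.18) and Rpl4 (-0.23, SE 0.08) fell. The list was not called (median 0.23, adjusted p = 0.0517, and 0.473 with an estimated correlation). At the preset correlation the list was called higher with the replicate number as a block (adjusted p = 0.0132) and with no filter (0.00855). It had a median of 0.05 under upper-quartile scaling, 0.07 under the stricter filter and -0.00 under library totals. It was also called higher without IP replicate 2 or 3, any 1 Input library, or replicate number 3 (adjusted p between 0.0103 and 0.0488). The median level of 21.6 CPM in IP and 19.1 in Input was low, and counts are uncertain because these genes have many near-identical copies. Rpl9 lost its call with the block (0.0681) and without any 1 Input library or replicate number 2 or 3 (0.0678 to 0.121). Rpl4 lost it with no filter (0.0749) and without IP replicate 2 or 3, any 1 Input library, or replicate number 2 or 3 (0.0814 to 0.243), and Rps4x and Rps27l without replicate number 1 or 3 (0.0540 to 0.116).

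Channels and receptors moved gene by gene, and their lists were not called. Of 20 channels of thalamic firing 6 rose, including the leak channel Kcnk3 (log2 fold change 0.95, SE 0.17) and the sodium channel subunit Scn8a (0.75, SE 0.09), and Kcnk9 (-1.94, SE 0.32), Kcnn2 (-1.29, SE 0.21), Kcnc2 (-1.05, SE 0.11) and Cacna1h (-0.84, SE 0.30) fell (median -0.11, -0.35 to -0.05 over all settings, camera direction up, adjusted p = 0.770). Of 29 glutamate and GABA-A receptor subunits 10 rose, including Grid1 (1.42), Gabra4 (0.94) and Grin1 (0.68), and 8 fell, including Grin2c (-2.71), Gria3 (-0.95) and Gria2 (-0.55), with a median of -0.01 (-0.26 to 0.09 over all settings, camera direction up, adjusted p = 0.770). Cacna1h lost its call in every fit without 1 library except that without IP replicate 2, and without replicate number 1 or 3 (adjusted p between 0.0758 and 0.257).

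Receptors that drugs act on also went both ways. Of 38 tested, 15 fell, among them Chrnb3 and Chrna3 (log2 fold changes -3.68 and -2.78), the dopamine receptors Drd1 (-4.23, SE 0.92) and Drd2 (-2.39, SE 0.24), the cannabinoid receptor Cnr1 (-2.73, SE 0.36) and the mu opioid receptor Oprm1 (-2.13, SE 0.19). The serotonin receptors Htr1f (2.03, SE 0.39) and Htr7 (1.62, SE 0.13), the dopamine receptor Drd5 (1.70, SE 0.33), the nicotinic subunit Chrnb2 (1.08, SE 0.11), the glutamate receptor Grm4 (0.88, SE 0.11) and the nociceptin receptor Oprl1 (0.68, SE 0.16) were among 10 that rose. The list was not called (median -0.08, -0.45 to 0.02 over all settings, adjusted p = 0.684). Drd1 lost its call without replicate number 3 (adjusted p = 0.0557).

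Immediate early genes, which neuronal activity induces, were not called as a list (median log2 fold change -0.40, -0.77 to -0.17 over all settings, adjusted p = 0.996). Of 14 tested, Egr3 (1.46, SE 0.27), Nr4a1 (0.85, SE 0.14), Egr1 (0.67, SE 0.08) and Dusp1 (0.39, SE 0.12) rose, and 6 fell, including Npas4 (-3.42, SE 0.65), Jun (-0.91, SE 0.20), Arc (-0.90, SE 0.22) and Fos (-0.78, SE 0.23). Dusp1 lost its call under upper-quartile scaling, library totals and the stricter filter (adjusted p between 0.139 and 0.308) and without Input replicate 2 or 3 or replicate number 2 or 3 (between 0.0647 and 0.167). Fos lost it without Input replicate 1 or 3 and replicate number 2 or 3 (between 0.0654 and 0.127), Arc without replicate number 2 or 3 (0.0661 and 0.0660) and Jun without replicate number 2 (0.0581).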

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

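Reads set aside as not uniquely aligned differed between the groups, in a part of the data that was not analysed by gene. They made up 49.7, 43.2 and 44.8% of all lines in IP replicates 1 to 3 (mean 45.9 ± 3.39%) and 34.0, 33.1 and 32.7% in Input replicates 1 to 3 (mean 33.3 ± 0.687%), with an exact p of 0.1, the smallest that 3 against 3 libraries allow. Assigned reads made up 43.7 ± 3.33% in IP and 45.4 ± 0.862% in Input (exact p = 0.6). Whether a read with several alignments was counted once or more often is unknown, so these may not be shares of reads.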

How the results depend on the processing

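Cbln1 kept its rise in all settings (log2 fold change 3.92 to 4.23). Of 3602 comparisons of 181 other genes, most of them named here, under 20 settings, 3447 counted as unchanged, 141 lost a call, 13 gained one and 1 reversed. Unchanged comparisons stayed on their side of the threshold or had no adjusted p under the setting. The reversal was in Pmch (1.45, adjusted p = 0.529), which was -5.39 without IP replicate 1 and 3.71 (adjusted p = 0.240) without Input replicate 1. The cause was not tested, but IP replicate 1 held nearly all its IP counts. Genes higher in IP numbered 3930, 2458 with library totals alone and 1484 with a fold threshold of 1.5; genes lower numbered 4100 and 2700 with that threshold, which by construction calls fewer. Leaving out libraries gave 2659 to 4392 higher and 3017 to 5066 lower genes, DESeq2 3996 and 5287, and scaling without Rn45s 3949 and 4086. Among fits that left out libraries, the share of main calls lost ran from 3.49% (without IP replicate 1) to 32.8% (without replicate number 3). Gene lists higher numbered 4, and 0 with the estimated correlation; lists lower numbered 11, 2 with the estimated correlation and 7 with the stricter filter, which tested fewer genes. With the replicate number as a block, 3793 genes were higher and 4038 lower. Of the 8030 calls of the main fit 574 were lost, and 375 other genes gained one. Cbln1 was at 4.17, all 15 lists kept their calls and 2 gained one (mural and cytosolic ribosomal). Among the 181 genes the block changed only Ttr, Kl, Lum, Rpl9 and Rab27a. Kcne2 and Xist, which are not among the 181, were 2 of the genes that gained a call (adjusted p = 0.0322 and 0.0251). Depth limits genes of few counts. Simulated 2-fold changes were found in 51.5% of cases, but that simulation gave 116 calls against 8030 in the real comparison, so the share may not hold here.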

Other observations

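The gene families below, Hcrt, Xist and Ddx3y, the tests of Gm2694 reads and the choroid plexus tests were chosen after their values were seen. The 3 pairs of neighbouring genes were noticed among the 10 largest increases, which were left out of the neighbour test. The splits, the length and scaling tests of oxidative phosphorylation and the test of long non-coding RNAs were written down before their results were seen, although the list's median under TMM was known.

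Mitochondrial ribosomal, vacuolar ATPase and Rab genes were called higher in IP. Of 76 mitochondrial ribosomal protein genes 66 rose and 0 fell, among them Mrps33 (log2 fold change 1.54) and Mrpl52 (1.52), with a median of 0.80 (camera adjusted p = 4.49e-15 over 15 families, and 0.0447 with an estimated correlation). Of 16 genes of the vacuolar ATPase, which acidifies vesicles and lysosomes, 12 rose, including Atp6v0c (1.43) and Atp6v1g2 (1.25), and Atp6v0e (-1.55) and Atp6v0a2 (-0.66) fell (median 0.73, adjusted p = 6.95e-05, and 0.0447 with an estimated correlation). Of 53 Rab GTPase genes, which direct vesicle traffic, 31 rose, including Rab26 (1.68), Rab4b (1.58) and Rab15 (1.27), and Rab3b (-2.38), Rab31 (-2.08), Rab37 (-1.75), Rab27a (-0.58) and Rab23 (-0.55) fell (median 0.55, adjusted p = 8.43e-05, and 0.0447 with an estimated correlation). Atp6v0a2 lost its call without replicate number 1 or 3 (adjusted p = 0.0590 and 0.111), and Rab27a with the replicate number as a block (0.0578), with no filter (0.0532), in every fit without 1 library except that without IP replicate 2, and without replicate number 1 or 3 (0.0621 to 0.246). Medians of lists matched on length and expression had a central 95% of 0.29 to 0.61 for mitochondrial ribosomal, 0.17 to 0.53 for Rab and 0.19 to 0.85 for vacuolar ATPase genes, and the vacuolar ATPase median lay inside its range. The lowest median over the scalings was 0.31 for Rab genes.

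Tubulin, proteasome, Eif and collagen genes were also called, and like that of the vacuolar ATPase the median of each of these 4 families lay inside the central 95% of lists matched on length and expression. Tubb2a (log2 fold change 1.53) and Tubb5 (1.26) were among 9 of 14 tubulin genes that rose (median 0.61, 0.38 at the lowest over the scalings, matched 0.18 to 0.91, adjusted p = 3.11e-04, but adjusted p = 0.263 with an estimated correlation), and Psma2 (1.07) and Psma7 (0.86) among 25 of 38 proteasome genes (median 0.46, 0.23 at the lowest over the scalings, matched 0.23 to 0.69, adjusted p = 3.41e-04, but adjusted p = 0.263 with an estimated correlation). Of 53 genes with symbols starting in Eif, most of them translation factors, 20 rose, including Eif1 (1.13) and Eif5a (0.94), and the kinase gene Eif2ak2 fell (-1.74). Their median was 0.29 (0.05 at the lowest over the scalings, matched 0.13 to 0.48, adjusted p = 0.00286, but adjusted p = 0.263 with an estimated correlation). Collagen genes, which code for extracellular matrix, were lower: 17 of 33 fell, including Col25a1 (-1.34), and Col9a2 rose (1.25), with a median of -1.66 (matched -2.54 to -0.92, adjusted p = 0.0120, but adjusted p = 0.263 with an estimated correlation). Col9a2 lost its call without Input replicate 2 or 3 and without replicate number 2 or 3 (adjusted p between 0.0715 and 0.103). The other 8 families, among them kinesins, potassium channels and synaptotagmins, were not called. Of these 8, the medians of protocadherins (0.11, matched -1.03 to -0.24) and of SR and hnRNP splicing factors (-0.05, matched 0.06 to 0.50) lay outside the range of matched lists. Their lowest medians over the scalings were -0.11 and -0.29.

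Gm2694 rose beside Cbln1, and its reads could be its own or come from Cbln1 on the opposite strand. The log2 ratio of Gm2694 to Cbln1 counts differed between IP and Input by -0.43 on average (-0.36, -0.51 and -0.41 in the replicate numbers), which excludes only that all its reads were a fixed share of Cbln1 reads, the same in IP and Input. On the GENCODE annotation the 2 genes share 0 exonic bases, which argues against reads within annotated Cbln1 exons as the source. The annotation used for the counts was not given, and whether that share differed between the groups was not measured. A contribution of Cbln1 reads is therefore not excluded. Gm2694 counts were 5.60% of Cbln1 counts at the lowest, in IP replicate 2. With that share of Cbln1 counts taken off in every library, Gm2694 was higher in IP in only 1 replicate number. This brings IP replicate 2 to 0 by construction. In 272 pairs of a long non-coding and a coding gene whose gene starts lie within 2000 bp on opposite strands, the log2 fold changes correlated (Spearman rho 0.21 across genes, permutation p = 5.50e-04). Regulation shared by neighbours would give this, and so would reads counted on the wrong strand. By gene start, Gm2694 lies 12140 bp from Cbln1 and is outside this class, although 9 of its 11 annotated transcripts start within the window.

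Oxidative phosphorylation genes are short, and short genes had higher log2 fold changes, so transcript length could account for their rise. The list's median of 0.99 lay above the central 95% of 10000 lists matched on length and expression (0.55 to 0.86, median 0.73). Against coding genes no longer than each member, a comparison added after that result, the median of 1.03 over 80 members lay above 0.58 to 0.91. Most of the size of the rise was shared by matched genes. Both ranges came from genes drawn independently, while members of the list varied together (estimated correlation 0.18). Such ranges may be too narrow, so length is not excluded as the whole cause. Under every scaling tried the list's median stayed at 0.75 or more. The largest shift these scalings gave to the median of all genes was -0.24, so they could not have taken 0.99 to 0. The test therefore cannot exclude a larger shift. Relative to the median of all genes, the list stood 1.06 higher under TMM and also under library totals. A change of scaling moves both medians by about the same amount, so this equality is no separate support. Whether the tagged neurons hold more of these RNAs than other cells or load more ribosomes on them was not tested.

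Choroid plexus genes were low in replicate 1, which may reflect what the dissection took in. Input replicate 1 had a median log2 ratio of -2.45 to the mean of the other Input libraries over 6 choroid plexus genes, of which Prlr was not low (-0.10, and 0.42 in IP), while 4 ependymal genes lay between -0.50 and 0.60. Ttr had 2.78, 477 and 542 CPM in Input replicates 1 to 3 and 0, 40.6 and 35.1 CPM in IP replicates 1 to 3. Lower depth is excluded, since 10000 lists matched on expression had a central 95% of -0.27 to 0.17. Without Ttr the Input median was -2.11, while the IP median was -1.36 with Ttr and -0.26 without it, which does not decide the matter for IP.

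Genes higher in IP lay next to each other more often than in shuffled orders. The hypothesis came from Cbln1 and Gm2694, Lypd6 and Lypd6b, and Ctxn3 and 1700011I03Rik among the 10 largest increases. With these 10 left out, 1066 genes called at least 2-fold higher formed 111 adjacent pairs, against 59 to 90 in the central 95% of 10000 shuffles (median 74). Pairs that share no bases numbered 94 (50 to 80 in shuffles), and 9 pairs had symbols that share their letters, as duplicated genes do. These 9 are too few to make up the excess of 111 over 90, so duplicated genes with such symbols are excluded as its whole cause. Domains of shared regulation could give it, and so could reads that run past a gene's end or duplicated genes with unlike symbols, which were not told apart.

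Of the 10 ways to split the 6 libraries into 3 and 3, only 1, the real one, called any gene (8030, against 0 as the highest of the others). For gene lists, too, only 1 split reached the real count of 15, with 13 as the highest of the others. The other 9 splits called 8 to 13 lists with the preset correlation and 0 with the estimated one, against 2 in the real split. At the preset correlation, the oxidative phosphorylation, astrocyte, oligodendrocyte and microglia lists were called in all 9. Of the lists called in the real split, the thalamic subdivision and red blood cell lists were called in 0 of them. Each of these 9 splits still holds a part of the difference between IP and Input. With 10 splits no share below 0.05 can be reached, so they cannot decide.

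Some single genes set replicates apart. Hcrt, the hypothalamic peptide orexin, had 13.2, 0.116 and 0.0957 CPM in Input replicates 1 to 3 and 1.14, 0.610 and 0.259 CPM in IP replicates 1 to 3. Xist, the RNA of the inactive X chromosome, had 165, 311 and 0 counts in Input replicates 1 to 3 and 87, 34 and 0 in IP replicates 1 to 3. The Y-linked gene Ddx3y was counted in all 6 libraries, at 28.1, 32.8 and 51.6 CPM in Input replicates 1 to 3 and 33.0, 28.9 and 40.2 CPM in IP replicates 1 to 3, so replicates 1 and 2 held both Xist and Y-linked RNA.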
